A study of Mus musculus with 12 samples.

How the data were processed

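Expression was measured with Affymetrix mouse arrays, 1 sample per array, in 12 samples of fetal liver KSL cells: WT and KO (Stat5a and Stat5b deleted), each unstimulated or stimulated with the cytokine mixture, 3 arrays per group described as biological replicates. Total RNA was extracted with Trizol and labelled with biotin. The duration of stimulation, the culture of the unstimulated cells and how the KSL cells were isolated are not given in the sources used here. The deposited values are log2 expression values, 1 per probe set and array, which the submitters' processing notes credit to RMA and Partek; RMA subtracts background, brings the probe values of the arrays to a common scale and summarises the probes of a probe set. The settings of both tools are not given in the sources used here. The scanner files were not used here, so background subtraction and summarisation could not be varied. Only the table of values of the series was used, and it was taken as deposited, with no further transformation.

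The table holds 45101 probe sets on 12 arrays, with values from 0.618 to 16.6. Array means lay between 5.828 and 5.829 and array medians between 4.197 and 4.365. Quantile normalization moved the median difference of all probe sets by at most 0.0149 and median centring by at most 0.0581. The 64 control probe sets were left out of the tests, which leaves 45037. Of these 34945 carry 1 gene symbol, 932 several and 9160 none in the annotation used, and these last are given as unnamed; 34741 symbols were matched by Entrez identifier to the current one. For gene lists and counts of genes, each of 18193 genes was represented by the probe set with the highest mean over the 12 arrays among those with 1 symbol. Detection calls were not used here, and a background level was set from the values: the lower peak of the probe sets' mean values (2.94) plus 3 times the spread on its left side (0.54), which gives 4.56. The mean of 23424 probe sets (52.0%) lies below it. A fold against a group below that level was computed with all values below it set to it and is given as a lower bound.

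The 5 comparisons were the stimulation response in WT and in KO cells, the genotype difference in stimulated and in unstimulated cells, and the genotype by stimulation interaction. They were fitted as contrasts of 1 linear model with 4 groups over all 12 arrays in limma 3.58.1 (R 4.3.3), with moderated variances (8 residual degrees of freedom, 10.2 with the prior), two-sided, and Benjamini-Hochberg adjustment over the 45037 probe sets within each comparison. Probe sets with an adjusted p under 0.05 are called, with no minimum fold. With 3 arrays per group the precision is set by the spread between replicates, and small changes go uncalled. The model was tested on simulated data with 4 groups of 3 arrays and true changes in 200 of the 45037 probe sets. It recovered 12% to 32% of changes of 1 (log2), 52% to 72% of changes of 2 and 88% to 96% of changes of 4. Of changes of 6 it recovered 92% to 100%, and false calls numbered 5 to 9 per comparison. The simulated noise was independent between arrays, whereas deviations of deposited arrays with the same replicate number correlated (median 0.314). The recovery rates and false calls therefore hold for arrays without shared deviations and may differ for the deposited ones.

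Arrays with the same replicate number carry the same date label in all 4 groups. Whether it dates the culture, the sort or the hybridization is not given. Whether the number pairs the samples was checked on deviations from the group means: of 18 pairs of arrays with the same number, 17 correlated above 0.1 (0.0849 to 0.725, median 0.314), pairs with other numbers lay between -0.485 and 0.00741, and 12 of 12 arrays correlated best with an array of their own number. The model had no term for the date, since none is stated for the study. The model with the replicate number as a block was run as an alternative, and its values are given where they change a call or move a count by more than 1.5 times. Differences within each date are given for the lead results and for lists past camera whose median changes sign between dates.

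In total 26 gene lists were tested: STAT5 targets, cytokine and growth factor receptors, STAT and JAK genes, CCN family, stem cell regulators, G2 and M phase, S phase, kinase inhibitors, ribosome biogenesis, immediate-early genes, MAP kinase feedback, BCL2 family, sterol synthesis, glycolysis, ATF4 targets, interferon response, class II antigen presentation, and markers of mast cells and basophils, eosinophils, neutrophils, monocytes and macrophages, erythroid cells, megakaryocytes, lymphoid cells, hepatocytes, and endothelial and stromal cells. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 26 lists, with the correlation estimated from the data as a companion. Fry tested each list against no change, without reference to other genes. With the preset correlation 12, 10, 9, 6 and 6 lists passed in the 5 comparisons in the order above; with the estimated one 2, 2, 0, 0 and 0 passed (sterol synthesis and STAT5 targets in both responses), and by fry 9, 12, 1, 0 and 1. Counts of members are given over all 45037 probe sets and adjusted over the list alone.

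Genes are named by a rule: Ccn3, Stat5a and Stat5b throughout; per comparison the 12 largest rises and 12 largest falls among called probe sets with 1 symbol and the same sign in all 3 pairs, or the 5 lowest p values where fewer than 5 passed; and up to 4 called members of each list, or up to 2 of the highest level where none was called. Where another gene is named, the text says so or it is another called member of a list. The lists, the naming rule, the model, the threshold and most alternatives were fixed before the data were examined. Chosen after seeing the data were the background level with the alternative that sets lower values to it, the alternative without WT stimulated 1 and KO unstimulated 1, and 3 added lists in the closing section (macrophage transcripts, germ line genes, NF-kappa-B targets). The last alternative rests on the difference between 3' and 5' control probe sets of Gapdh, where RNA degradation and amplification raise the value. By group it averaged 2.34 (SD 0.38) in unstimulated WT, 2.21 (SD 0.84) in stimulated WT, 2.63 (SD 1.18) in unstimulated KO and 1.66 (SD 0.13) in stimulated KO cells.

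The alternatives tried were the replicate number as a fixed or a random block (estimated correlation 0.241), quantile normalization, median centring, leaving out probe sets with a mean below 4.35, moderation with trend and robust options, no moderation, only the compared groups in the fit, array weights, 1 probe set per gene, leaving out each array or each replicate number, and those chosen later. For the lists they were the mean of all probe sets of a gene, the estimated correlation, fry, the replicate block and those chosen later. For the relation of both responses, all genes or only the genes called in WT cells were used. Splits of the arrays into other groups were counted for each comparison.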

Results

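KSL cells are hematopoietic stem and progenitor cells that carry Kit and Sca-1 and lack lineage markers. Expression was measured in KSL cells from mouse fetal liver, either control (WT) or lacking the transcription factors Stat5a and Stat5b (KO), left unstimulated or stimulated with a mixture of the cytokines SCF, TPO, FL, IL-3 and IL-6. Each of the 4 groups held 3 arrays, and arrays with the same replicate number share a date. Values within each of the 3 dates are given for the lead results, and for each list past camera whose median changes sign between dates. The comparisons ask which genes change with stimulation, and which of these responses, that of the stem cell regulator Ccn3 (Nov) in particular, depend on STAT5. No group is described as cultured without the cytokines. Effects of culture therefore cannot be told apart from those of the cytokines in any stimulation response below. Differences are log2 values with the standard error (SE) of the limma model and its adjusted p. On each array 46.7% to 48.2% of probe sets lay above a background level of 4.56 (log2), and folds against a group below that level are given as lower bounds.

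The deleted genes were near background in KO cells and high in WT cells. Stat5b averaged 10.75 (log2) in unstimulated and 9.40 in stimulated WT cells, against 2.44 and 2.55 in KO cells. The difference was -8.31 (SE 0.23, adjusted p = 1.41e-07) without and -6.85 (SE 0.23, adjusted p = 1.01e-06) with stimulation. Stat5a averaged 9.06 and 8.14 in WT cells against 3.46 and 3.59 in KO cells. It differed by -5.60 (SE 0.30, adjusted p = 5.9e-05) and -4.54 (SE 0.30, adjusted p = 0.000157). Relative to the background level these are at least 72.8-fold and 28.6-fold lower for Stat5b, and at least 22.5-fold and 11.9-fold lower for Stat5a. Each gene has a second probe set, which was near background in WT cells too and passed in neither genotype comparison (Stat5b -1.22 and -1.39, Stat5a -0.88 and -0.97). Stat5b was lower in stimulated than in unstimulated WT cells by -1.35 (SE 0.23, adjusted p = 0.00905), and the Stat5a value there was -0.92 (SE 0.30, adjusted p = 0.119, or 0.0422 with the replicate block).

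**Figure D1:**
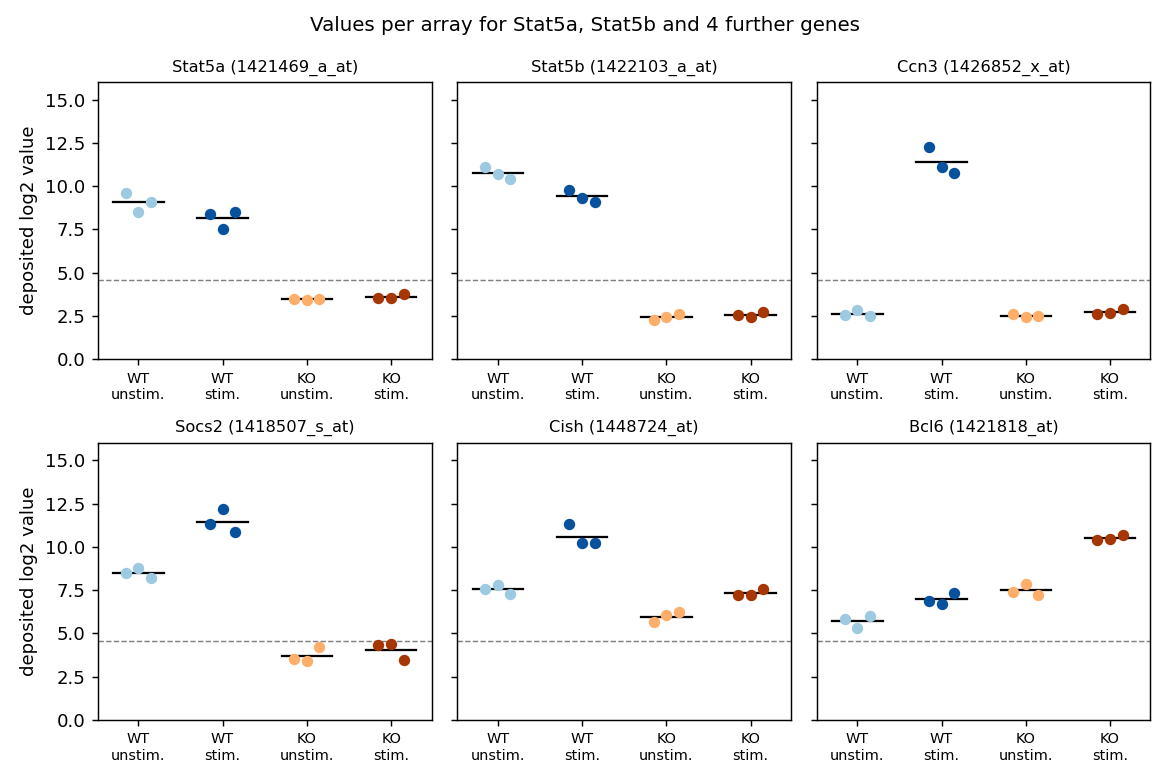
Deposited log2 values of Stat5a, Stat5b, Ccn3, Socs2, Cish and Bcl6 (y axis, 1 probe set each) on the 12 arrays in the 4 groups (x axis); each point is 1 array, the short horizontal line the group mean and the dashed line the background level of 4.56. Ccn3 averaged 11.37 in stimulated WT cells and 2.51 to 2.71 in the other groups, and Bcl6 was highest in stimulated KO cells, at 10.51.

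Stimulated WT cells gained Ccn3, interferon-response and sterol synthesis genes, and Fos, Fosb and the stem cell genes Robo4 and Esam fell. Ccn3, a secreted matricellular protein, rose from 2.62 to 11.37, a change of 8.75 (SE 0.32, adjusted p = 3.08e-06, n = 3 arrays per group) or at least 112-fold, and by 9.73, 8.24 and 8.28 within the 3 dates. Its other probe set rose by 6.89 (SE 0.30, adjusted p = 8.08e-06). In all, 1109 probe sets were higher and 1080 lower, 2189 of 45037 tested, and 983 and 944 of them differed by at least 2-fold. They include 1494 named genes.

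The largest named rises in WT cells were led by Clec4n (dectin-2, a receptor for fungal sugars), at 9.74 (SE 0.59, adjusted p = 4.58e-05), or at least 259.9-fold. Also among them were the interferon-induced genes Ifit1 (9.22, SE 1.20), Ifit3 (8.05, SE 1.28), Mx1 (7.78, SE 0.97), Usp18 (7.67, SE 0.80) and Iigp1 (7.59, SE 1.07), and the chemokine Cxcl10 (8.40, SE 1.13). The lipases Lpl (7.77, SE 0.84, from 6.86 to 14.63) and Lipg (7.77, SE 0.99) rose as well. So did the lysosomal transporter Slc15a3 (8.32, SE 1.12), the protease inhibitor Serpinb2 (7.84, SE 0.89) and the fatty acid receptor Gpr84 (7.52, SE 0.37, adjusted p = 1.48e-05). Among the falls were Fosb (-7.43, SE 0.78) and Fos (-4.45, SE 0.67), subunits of the AP-1 transcription factor, and Jakmip1 (-6.43, SE 0.80). The germ cell RNA helicase Ddx4 (-5.89, SE 0.83), the hepatic nuclear receptor Hnf4a (-5.28, SE 0.67) and the metalloproteinase inhibitor Timp2 (-5.13, SE 0.57) fell too. The remaining falls were Coro2b (-4.86, SE 0.83), the class II antigen presentation gene H2-Ob (-4.81, SE 0.48), the lipid carrier Apoe (-4.54, SE 0.62), the receptor Robo4 (-4.38, SE 0.91), Gdf3 (-4.21, SE 0.95) and the sterol hydroxylase Cyp27a1 (-4.14, SE 0.38). Adjusted p values of these genes lay between 1.48e-05 and 0.0331, and each moved the same way in 3 of 3 pairs of arrays. Some of them passed on only part of their probe sets. These were Lipg (2 of 3), Jakmip1 and Hnf4a (2 of 4 each), Timp2 (3 of 6) and Cyp27a1 (1 of 2).

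Sterol synthesis was the most uniform group in WT cells: 17 of 18 measured genes rose (18 adjusted over the list alone), with a median of 2.57 and 2.40 to 2.94 within the dates (camera adjusted p = 1.16e-33, and adjusted p = 0.00579 with an estimated correlation). Examples are Mvd (5.13, SE 0.29), Cyp51 (4.43, SE 0.33), Fdps (4.11, SE 0.31) and Msmo1 (3.90, SE 0.18). Of 19 STAT5 targets, 10 rose and none fell (14 adjusted over the list alone), with a median of 1.95 and 1.18 to 2.20 within the dates (camera adjusted p = 1.55e-09, and adjusted p = 0.00579 with an estimated correlation). They included Socs3 (4.68, SE 0.90), Osm (4.67, SE 0.52), Pim2 (3.76, SE 0.81) and Il2ra (3.55, SE 0.77). Of 27 interferon-response genes 19 rose (25 adjusted over the list alone), with a median of 4.21 (camera adjusted p = 5.59e-23, and adjusted p = 0.168 with an estimated correlation). That median was 4.89, 1.62 and 5.72 within the dates. The number that rose was 11 without the arrays WT stimulated 1 and KO unstimulated 1, which had the highest 3' to 5' signal difference of Gapdh, a sign of RNA quality (3.18 and 3.99 log2, against 1.53 to 2.66 on the other arrays).

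Several smaller shifts upward in WT cells passed camera and were lost with an estimated correlation. Of 17 amino acid stress and ATF4 targets 5 rose (6 adjusted over the list alone, 8 with the replicate block), with a median of 0.91 (0.66 to 1.32 within the dates, camera adjusted p = 4.55e-07, and adjusted p = 0.121 with an estimated correlation). Among them were the pseudokinase Trib3 (6.39, SE 0.35), the cystine transporter subunit Slc7a11 (5.09, SE 0.96) and Chac1 (4.43, SE 0.45). Of 24 monocyte and macrophage markers 6 rose (7 adjusted over the list alone), with a median of 0.76 (0.15 to 1.48 within the dates, camera adjusted p = 0.000372, and adjusted p = 0.429 with an estimated correlation). These included Cd14 (6.21, SE 1.34), Fcgr1 (5.77, SE 1.24) and Ctss (4.55, SE 0.93), and only 1 passed without WT stimulated 1 and KO unstimulated 1. Of 14 BCL2 family genes 3 rose (3 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.00445, and adjusted p = 0.0807 with an estimated correlation): proapoptotic Pmaip1 (4.82, SE 0.93) and antiapoptotic Bcl2l1 (1.97, SE 0.34) and Bcl2l2 (1.57, SE 0.30). In glycolysis 3 of 17 genes rose and 1 fell (6 and 2 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.0329, and adjusted p = 0.542 with an estimated correlation). Those were Aldoc (2.50, SE 0.50), the glucose transporter Slc2a1 (1.29, SE 0.27) and Hk2 (0.81, SE 0.17) against Pfkm (-1.47, SE 0.33). In ribosome biogenesis 1 of 28 genes rose, Heatr1 (0.69, SE 0.17; none adjusted over the list alone), with a median of 0.19 (-0.10, 0.61 and 0.09 within the dates, camera adjusted p = 0.0329, and adjusted p = 0.606 with an estimated correlation).

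Stem cell and erythroid genes shifted downward in WT cells, as did cell cycle genes by less. Among 37 hematopoietic stem cell regulators, Robo4 and Esam (-3.00, SE 0.71) fell and Ccn3 rose (4 lower and 1 higher adjusted over the list alone, 5 lower with the replicate block). The median was -0.71 (-0.80 to -0.57 within the dates, camera adjusted p = 0.0013, and adjusted p = 0.429 with an estimated correlation). Of 26 erythroid markers, Aqp1 (-3.88, SE 0.75) and Car2 (-0.91, SE 0.23) fell (3 lower and 1 higher adjusted over the list alone, 9 lower and 1 higher with the replicate block). The median was -1.45 (-1.90 to -1.11 within the dates, camera adjusted p = 0.00105, and adjusted p = 0.513 with an estimated correlation). S phase genes had a median of -0.27 with 1 of 29 lower, Pold1 (-0.92, SE 0.19, 1 adjusted over the list alone, 2 with the replicate block, camera adjusted p = 0.0077, and adjusted p = 0.168 with an estimated correlation). The G2 and M phase genes Ccnb2 (-1.14, SE 0.20) and Cenpf (-0.91, SE 0.19) fell, 2 of 24 (5 adjusted over the list alone, 4 with the replicate block), with a median of -0.22 (-0.51, 0.06 and -0.16 within the dates, camera adjusted p = 0.0217, and adjusted p = 0.604 with an estimated correlation, and 0.284 by camera without WT stimulated 1 and KO unstimulated 1).

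The other 14 lists did not pass camera in WT cells, but most held genes that did pass. The beta chains of the IL-3 receptor family rose, Csf2rb2 by 6.34 (SE 0.48) and Csf2rb by 3.26 (SE 0.35), and Flt3, the receptor for FL, fell (-3.26, SE 0.64). In all, 4 of 15 receptors were higher and 2 lower (5 and 3 adjusted over the list alone). The cell cycle inhibitor Cdkn1a rose by 6.40 (SE 0.73), 1 of 7 inhibitors, and Egr3 by 5.64 (SE 0.82) against the falls of Fos and Fosb among 20 immediate-early genes (3 higher and 5 lower adjusted over the list alone). In antigen presentation Cd74 rose (6.25, SE 0.89) and H2-DMa (-2.98, SE 0.47) and H2-Oa (-2.13, SE 0.28) fell, of 7 genes. Single markers of other cell types rose. They were granzyme Gzmb (6.37, SE 1.17, 1 of 20 mast cell and basophil genes), Mmp8 (6.16, SE 0.79, 1 of 18 neutrophil genes) and Cd9 and Plek (2.32 and 2.08, 2 of 20 megakaryocyte genes, with Gp9 lower at -2.39). Afp (4.56, SE 0.57, 1 of 22 hepatocyte genes, with Hnf4a and Krt18 lower) and Flt1 (3.31, SE 0.77, 1 of 22 endothelial and stromal genes) rose too. In the lymphoid list Rag1 (-1.42) and Satb1 (-1.88) fell, 2 of 21, and in the MAP kinase feedback list Spred1 rose (1.67), 1 of 12. Ccn3 was the 1 gene of 6 in the CCN family that passed, while Siglecf of the 6 eosinophil markers (-2.28, adjusted p = 0.0618) and Stat3 (0.42) of the 8 STAT and JAK genes did not. Median and mean differ in sign for the CCN family (-0.05 and 1.21), kinase inhibitors (-0.18 and 0.67), mast cells (-0.05 and 0.89), antigen presentation (-0.27 and 0.37, tested downward) and hepatocytes (0.06 and -0.14). With the replicate block 4633 probe sets were called in WT cells, 2172 higher and 2461 lower, among them 2186 of the 2189. With values below background set to that level, 1028 were called, and the calls of Coro2b (adjusted p = 0.0692), Robo4 (0.0724) and Gdf3 (0.0765) were lost.

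Stimulated KO cells gained largely the genes gained in WT cells, without Ccn3. The Ccn3 values were 2.51 before and 2.71 after stimulation, a difference of 0.20 (SE 0.32, adjusted p = 0.819; 0.01, 0.21 and 0.39 within the dates). The largest rise was that of Cxcl10, 9.87 (SE 1.13, adjusted p = 0.00109), and 24 of 27 interferon-response genes rose. In all, 1511 probe sets were higher and 1863 lower, 3374 of 45037, with 1291 and 1613 at 2-fold or more and 2156 named genes.

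Named rises in KO cells that are not among those named in WT cells were Slfn4, an interferon-inducible gene of myeloid cells (9.84, SE 1.76), the metalloproteinase Adam8 (7.95, SE 0.57, adjusted p = 0.000108) and the prostaglandin synthase Ptgs2 (7.84, SE 0.88). These 3 genes were not particular to KO cells. Their means in WT cells went from 2.22 to 9.40 (Slfn4), 3.95 to 10.05 (Adam8) and 4.39 to 11.46 (Ptgs2) with stimulation. Lpl rose by 9.04 (SE 0.84), or 525-fold, Clec4n by at least 164-fold (adjusted p = 7.72e-05), Slc15a3 by 9.18 (SE 1.12) and Lipg by 8.73 (SE 0.99). The interferon-induced Ifit1 (9.31, SE 1.20), Ifit3 (8.98, SE 1.28), Iigp1 (8.49, SE 1.07) and Mx1 (8.34, SE 0.97) were among the rises here too. Falls were led by Fosb (-7.10, SE 0.78), Jakmip1 (-6.97, SE 0.80), Hnf4a (-4.94, SE 0.67) and the water channel Aqp1 (-4.69, SE 0.75). Gimap6 (-4.67, SE 1.19), Btbd11 (-4.62, SE 0.76), Timp2 (-4.58, SE 0.57), Ddx4 (-4.53, SE 0.83), Nrep (-4.49, SE 0.65), the phosphodiesterase Pde4b (-4.49, SE 0.47), H2-Ob (-4.47, SE 0.48) and Aff3 (-4.47, SE 0.55) completed them. Adjusted p values of these genes lay between 7.72e-05 and 0.0413. Some of them passed on only part of their probe sets. These were Pde4b (1 of 6), Gimap6 and Aff3 (1 of 2 each), Jakmip1 and Hnf4a (2 of 4 each), Timp2 (3 of 6) and Lipg (2 of 3).

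The sterol synthesis genes rose in KO cells as well, 17 of 18 (18 adjusted over the list alone), with a median of 2.38 (2.38 to 2.59 within the dates, camera adjusted p = 3.8e-28, and adjusted p = 0.0144 with an estimated correlation), for example Fdps (4.63, SE 0.31) and Cyp51 (4.26, SE 0.33). Of 19 STAT5 targets 7 rose (9 adjusted over the list alone), with a median of 1.11 (0.71 to 1.44 within the dates, camera adjusted p = 3.15e-06, and adjusted p = 0.0144 with an estimated correlation). Osm (4.65, SE 0.52), Socs3 (3.62, SE 0.90), the repressor Bcl6 (3.02, SE 0.25) and Bcl2l1 (1.71, SE 0.34) were among them, whereas Pim2 (0.80, SE 0.81), Il2ra (-0.05, SE 0.77) and Socs2 (0.35) did not pass. The interferon-response median was 4.90 (6.25, 3.00 and 5.38 within the dates; 25 higher adjusted over the list alone, camera adjusted p = 4.71e-24, and adjusted p = 0.184 with an estimated correlation), and 16 members passed without WT stimulated 1 and KO unstimulated 1. The ATF4 targets had 7 of 17 higher (8 adjusted over the list alone) and a median of 1.34 (camera adjusted p = 5.09e-08, and adjusted p = 0.085 with an estimated correlation), with Trib3 at 7.37 (SE 0.35) and Slc7a11 at 6.15 (SE 0.96). Monocyte and macrophage markers had 7 of 24 higher (12 adjusted over the list alone, 12 with the replicate block) and a median of 1.26 (camera adjusted p = 3.15e-06, and adjusted p = 0.31 with an estimated correlation), led by Cd14 (7.84, SE 1.34) and Fcgr1 (6.68, SE 1.24). In the BCL2 family 4 of 14 genes rose, Pmaip1 (3.82), Bcl2l1, Bcl2l2 and Bid (0.65). With adjustment over the list alone, and with the replicate block, 7 were higher and 1 lower (median 0.58, camera adjusted p = 0.00784, and adjusted p = 0.085 with an estimated correlation). Gzmb (6.10, SE 1.17) and the chemokines Ccl4 (5.91, SE 1.29) and Ccl3 (5.89, SE 1.44) were the 3 of 20 mast cell and basophil genes that rose (3 adjusted over the list alone; median 0.18, camera adjusted p = 0.0271, and adjusted p = 0.44 with an estimated correlation).

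Of 37 stem cell regulators 7 fell in KO cells (9 adjusted over the list alone), among them Robo4 (-3.79, SE 0.91), Esam (-3.71, SE 0.71), Fgd5 (-3.05, SE 0.65) and Prdm16 (-2.90, SE 0.74). The list median was -0.55 (-0.96 to -0.25 within the dates, camera adjusted p = 0.000473, and adjusted p = 0.349 with an estimated correlation). The erythroid list had a median of -1.28 (-2.48 to -0.37 within the dates, camera adjusted p = 0.00784, and adjusted p = 0.576 with an estimated correlation). In it Aqp1 and Car2 (-1.03) were lower and the embryonic globin Hbb-y (4.58, SE 1.01) and the transferrin receptor Tfrc (1.72, SE 0.36) higher (3 lower and 2 higher adjusted over the list alone, 11 lower with the replicate block). S phase genes had 2 of 29 lower, Pole (-1.11) and Pold1 (-0.89) (4 adjusted over the list alone and with the replicate block), and a median of -0.14 (camera adjusted p = 0.04, or 0.0522 with the replicate block, and adjusted p = 0.31 with an estimated correlation).

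Among the 16 lists that did not pass camera in KO cells, Csf2rb2 (6.38, SE 0.48) and Csf2rb (3.14, SE 0.35) rose and Flt3 fell (-2.93, SE 0.64), 4 of 15 receptors being higher and 2 lower. Stat2 rose (4.92, SE 1.26; 1 of 8 STAT and JAK genes), as did Cdkn1a (5.89) and Cdkn2b (1.66) of 7 kinase inhibitors, Spred1 (1.95) and Dusp4 (3.14) of 12 MAP kinase feedback genes and Slc2a1 (1.12) of 17 glycolysis genes, where Pfkm fell (-1.34). Among immediate-early genes Egr3 rose (6.93, SE 0.82) and Fosb and Fos fell, and in antigen presentation Cd74 rose (4.24, SE 0.89) and H2-DMa (-4.09) and H2-Oa (-2.30) fell. G2 and M phase genes had 4 of 24 lower, for example Ccnb2 (-1.16) and Mki67 (-1.03). Of other cell types, Mmp8 (5.54; neutrophils), Cd9 and Plek (2.42 and 2.16; megakaryocytes), Afp and Ttr (4.45 and 0.65; hepatocytes), Ighm (2.74; lymphoid cells) and Kdr (3.68; endothelial cells) rose. Siglecf (-2.83; eosinophils), Krt18 (-4.09; hepatocytes, with Hnf4a), Pdgfrb (-2.48; stromal cells) and the lymphoid genes Rag2 (-2.39), Cd79b (-1.68) and Vpreb1 (-0.67) fell. None of the 6 CCN genes and none of the 28 ribosome biogenesis genes passed limma's test in KO cells (0 and 3 at an unadjusted p under 0.05; Ccn1 -0.11, Ncl 0.32). Median and mean differ in sign for kinase inhibitors (-0.10 and 0.92) and for endothelial and stromal genes (-0.07 and 0.11, tested downward). Megakaryocyte genes passed camera only without WT stimulated 1 and KO unstimulated 1 (median 0.37, adjusted p = 0.0396, against 0.09 and 0.21 with them). The replicate block called 6368 probe sets in KO cells, 2736 higher and 3632 lower, among them 3372 of the 3374. With values below background set to that level, 1712 were called, and the calls of Slfn4 (adjusted p = 0.0701), Hnf4a (0.0605) and Gimap6 (0.111) were lost.

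Across genes the responses of WT and KO cells ran close together. With 1 probe set for each of 18193 genes, 1109 genes were called in WT cells and 1552 in KO cells, 1771 in either. Of these, 451 rose in both (23.2 expected if calls fell independently over all genes) and 439 fell in both (23.8 expected), while no gene passed in opposite directions. The expected counts treat every gene as equally likely to be called. Both responses share 1 estimate of each gene's spread, and genes below background can hardly fall, so those counts may be too low. Over the 1771 genes 99.2% had the same sign, Pearson's r across genes was 0.952 (0.897 to 0.948 within the dates) and the slope of KO on WT values was 1.04 (0.973 to 1.02 within the dates). Genes are not independent replicates, so no p is attached to r.

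**Figure D2:**
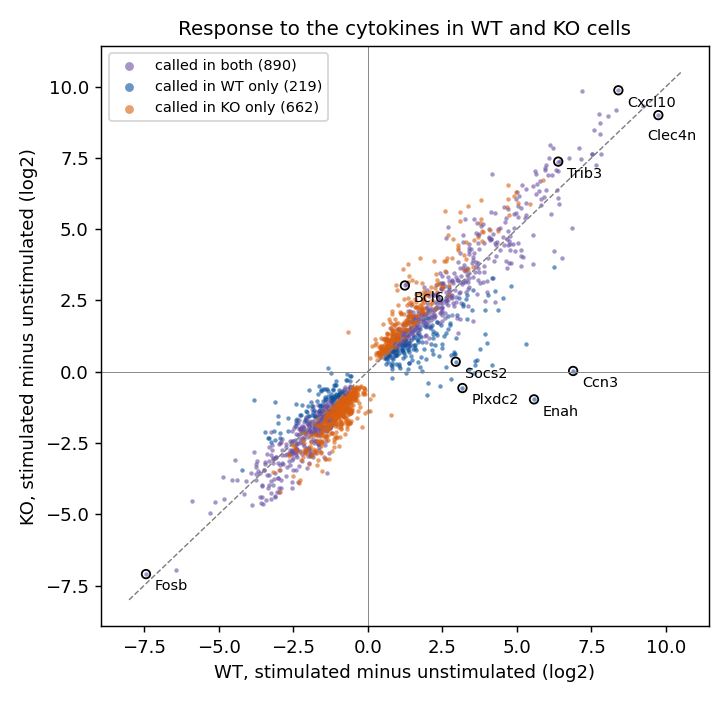
Log2 response to stimulation in WT cells (x axis) and KO cells (y axis) of the 1771 genes called in either response, each point 1 gene, coloured by where it was called; the dashed line marks equal responses and circles mark named genes. Most points follow the line (r = 0.952), while Ccn3 lies far below it.

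**Figure D3:**
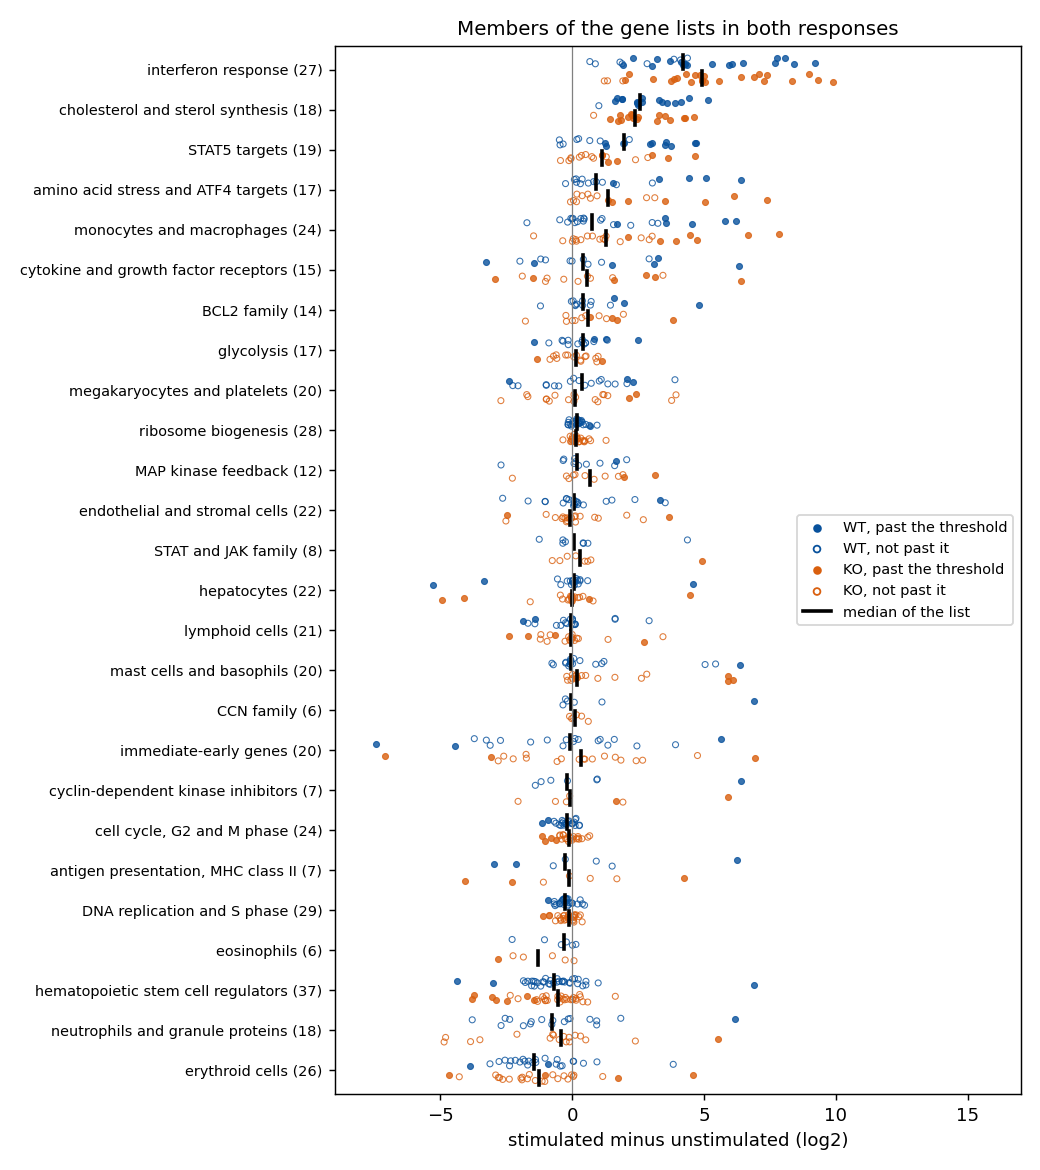
Log2 response to stimulation (x axis) of every measured member of each gene list in WT cells (blue) and KO cells (orange); filled points passed the adjusted threshold and the black bar is the list's median. Sterol synthesis (medians 2.57 and 2.38) and interferon-response genes (4.21 and 4.90) lie to the right in both genotypes.

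Between stimulated KO and stimulated WT cells few genes were called, and most of these were lower in KO cells. Ccn3 was lower by -8.66 (SE 0.32, adjusted p = 1.7e-06; -9.68, -8.43 and -7.88 within the dates), or at least 112-fold, and by -7.08 (SE 0.30) on its other probe set. Socs2, a suppressor of cytokine signalling, differed by -7.37 (SE 0.38, adjusted p = 2.07e-05), at least 117-fold lower, having risen in WT cells from 8.48 to 11.44 while KO values were 3.71 and 4.06. Bcl6 was the largest difference upward, 3.55 (SE 0.25, adjusted p = 0.000274) or 11.7-fold higher, with means of 5.71 and 6.96 in WT and 7.49 and 10.51 in KO cells before and after stimulation. In all, 25 probe sets were lower and 4 higher, 29 of 45037, covering 20 named genes.

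Enah, an actin regulator, was lower in stimulated KO cells by -6.33 (SE 0.58, adjusted p = 0.00192), at 5.17 against 11.49, and Plxdc2 by -5.78 (SE 0.43, adjusted p = 0.000433), below background against 9.98. Cish, another suppressor of cytokine signalling, was lower by -3.25 (SE 0.29, adjusted p = 0.00192), although its mean was higher with than without stimulation in KO cells too (7.33 and 5.97, against 10.58 and 7.55 in WT cells). Further lower were the TNF receptor family member Tnfrsf9 (-3.18, SE 0.45), Stxbp6 (-3.40, SE 0.26) and Shroom3 (-2.83, SE 0.36). So were Fermt2 (-2.74, SE 0.34) and Unc45b (-2.54, SE 0.30), and the adjusted p of these genes ran from 0.000433 to 0.0498. Fermt2 passed on 1 of its 3 probe sets, and its brightest went the other way and did not pass. Sema7a (-2.43), the cytokine Lta (-2.35), Ccdc40 (-1.99) and Cpne8 (-1.25) also passed and are named after their values were seen. Higher, besides Bcl6, were the chemokine receptor Ccr2 (2.66, SE 0.36, adjusted p = 0.036, or 0.0725 with the replicate block) and Gpr174 (2.31, SE 0.32, adjusted p = 0.0388). Bcl6 passed on 1 of its 2 probe sets, Ccr2 on 1 of 4, Gpr174 on 1 of 2, Socs2 and Enah on 3 of 6 each, Plxdc2 on 2 of 3, Stxbp6 and Sema7a on 1 of 2 each, Tnfrsf9 and Cpne8 on 1 of 3 each and Shroom3 on 1 of 5. Cish, Unc45b, Lta and Ccdc40 have 1 probe set each.

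Of 19 STAT5 targets, Socs2 and Cish were lower and Bcl6 higher in stimulated KO cells (4 lower and 2 higher adjusted over the list alone), the median was -0.03 and camera gave an adjusted p of 0.0664. Median and camera look for a shift in 1 direction, and members moved both ways. Fry taken over both directions gave an adjusted p of 1.27e-08. It gave the same value for stem cell regulators, where Ccn3 alone was called. Il2ra (-3.99, SE 0.77, adjusted p = 0.258) and Pim2 (-3.04, SE 0.81, adjusted p = 0.887), both called in the WT response, did not pass here over all probe sets. Camera passed 9 of the 26 lists, each with an adjusted p of 0.533 with an estimated correlation. Interferon-response genes were higher in KO cells by a median of 0.83 (1 of 27 members at an unadjusted p under 0.05, none past limma's threshold; 0.67, 1.38 and 0.23 within the dates, camera adjusted p = 2.48e-05). Monocyte and macrophage markers were higher by 0.61 (3 of 24 unadjusted, adjusted p = 0.000157) and mast cell genes by 0.22 (0.28, 0.26 and -0.01 within the dates, 2 of 20 unadjusted, adjusted p = 0.0293). Megakaryocyte genes were higher by 0.46, but by 1.52, 0.17 and -0.52 within the dates (0 of 20 unadjusted, adjusted p = 0.0293). No probe set that represents a gene of the monocyte and macrophage, mast cell or megakaryocyte lists was past limma's threshold. Ccr2, a monocyte and macrophage marker, passed on a probe set that does not represent it in the list (2.66, adjusted p = 0.036 in limma). Stem cell regulators were lower by a median of -0.21 (adjusted p = 0.00457), but by -0.24, -0.10 and 0.12 within the dates, with Ccn3 the 1 called. Erythroid genes (-0.67, 2 of 26 unadjusted, adjusted p = 0.00128), sterol synthesis (-0.18; 0.12, -0.17 and -0.39 within the dates, 0 of 18 unadjusted, adjusted p = 0.0293) and class II antigen presentation (-0.29; -0.46, -0.57 and 0.00 within the dates, 1 of 7 unadjusted, adjusted p = 0.0293) were lower as well. For the last 3 the call was lost without WT stimulated 1 and KO unstimulated 1 (0.225, 0.157 and 0.185), and the erythroid median was then -0.05. Passing only without those arrays, all upward, were immediate-early genes (median 0.49, camera adjusted p = 0.0242), MAP kinase feedback (0.51, 0.0432), STAT and JAK genes (0.32, 0.0432) and eosinophil markers (0.31, 0.0198). The CCN family passed downward (0.0291, or 0.0792 with the replicate block) with a median of 0.01 (-0.04, -0.08 and 0.08 within the dates) and a mean of -1.24, since Ccn3 alone differed. The replicate block called 44 probe sets, 39 lower and 5 higher, 25 of them among the 29, and 15 were called without WT stimulated 1 and KO unstimulated 1. With values below background set to that level the calls of Stxbp6, Tnfrsf9, Shroom3, Unc45b and Gpr174 were lost (adjusted p = 0.158 to 1).

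**Figure D4:**
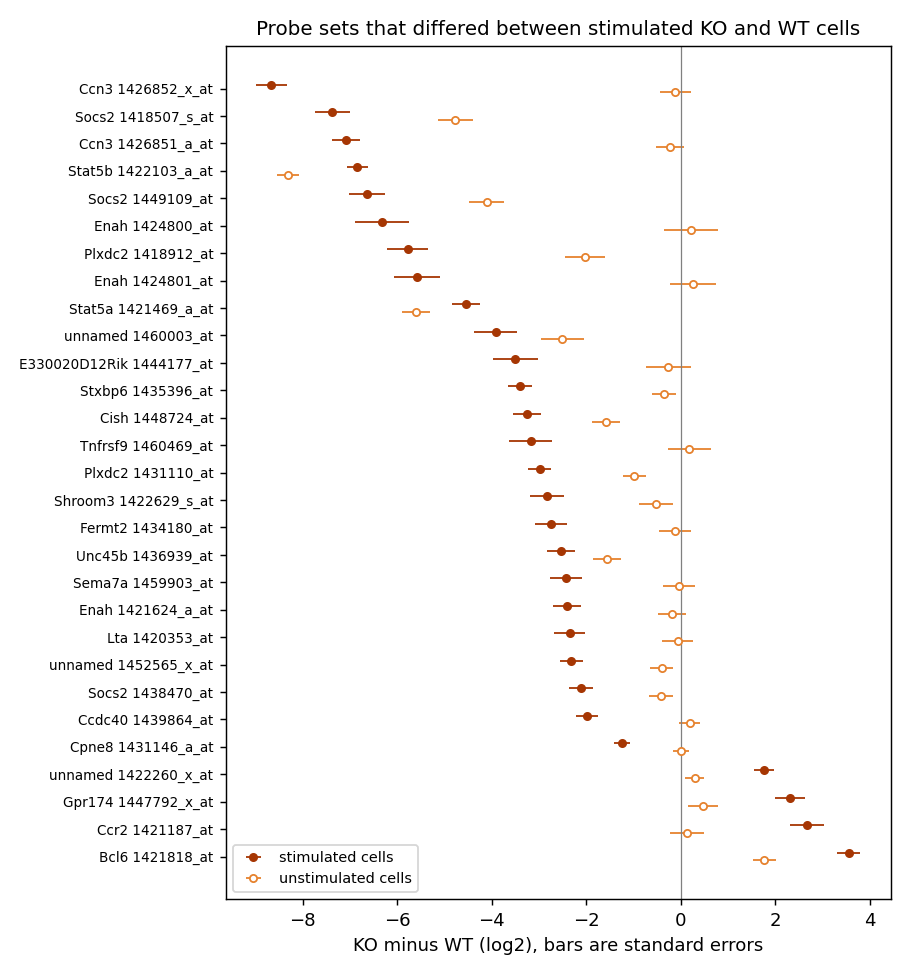
Difference KO minus WT (x axis, log2, bars are the SE of the model) of the 29 probe sets called in stimulated cells (y axis), shown for stimulated (filled) and unstimulated cells (open). Differences in stimulated cells run from -8.66 (Ccn3) to 3.55 (Bcl6), and Stat5a, Stat5b and Socs2 are also lower in unstimulated KO cells.

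Without stimulation the deleted genes and Socs2 were the genes called between KO and WT cells. Socs2 was lower by -4.77 (SE 0.38, adjusted p = 0.00202), at least 15.1-fold, and by -4.97, -5.38 and -3.96 within the dates. A second probe set of it passed as well (-4.11, adjusted p = 0.00653). That second call was lost with values below background set to that level (adjusted p = 0.169). Ccn3 was at background in both genotypes (2.51 and 2.62, a difference of -0.12, adjusted p = 1). Limma called 4 probe sets, all lower in KO cells (422 at an unadjusted p under 0.05, where 2252 are expected by chance). The expected count holds for arrays without shared deviations. Deviations of same-numbered KO and WT arrays in 1 stimulation state correlated at 0.308 to 0.725, and the model has no term for this. Its p for the genotype differences may therefore be too high, also in stimulated cells (1242 at an unadjusted p under 0.05). A short list of calls does not show that other genes were alike. The next genes by p did not pass over all probe sets: Bcl6 at 1.77 (SE 0.25, adjusted p = 0.209, positive in 3 of 3 pairs) and Clcn2 at -2.02 (SE 0.34, adjusted p = 0.899). Adjusted over the list alone, 2 of 19 STAT5 targets were lower and 1 higher in unstimulated KO cells. The list median was 0.01 (camera adjusted p = 0.694), and fry taken over both directions gave an adjusted p of 3.11e-07.

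Camera passed 6 lists in unstimulated cells, none of them with an estimated correlation, and none of their members was past limma's threshold. Erythroid genes were lower in KO cells by a median of -0.65 (-1.02, -0.70 and -0.34 within the dates; 4 of 26 at an unadjusted p under 0.05, camera adjusted p = 9.39e-08, and adjusted p = 0.589 with an estimated correlation), for example Tfrc (-0.82, SE 0.36). Eosinophil markers were higher by a median of 0.86 (1.81, 0.64 and 0.26 within the dates, 2 of 6 higher adjusted over the list alone and unadjusted, camera adjusted p = 5.55e-06, and adjusted p = 0.0973 with an estimated correlation). Neutrophil genes were higher by 0.78 (0 of 18 unadjusted, camera adjusted p = 6.81e-06, and adjusted p = 0.589 with an estimated correlation), but by 2.86, 0.09 and -0.07 within the dates, and by -0.01 without the arrays of highest 3' to 5' difference, of which KO unstimulated 1 is one. Megakaryocyte genes (0.30; 0.86, 0.11 and -0.26 within the dates, 0 of 20 unadjusted, camera adjusted p = 0.0061) moved likewise, at -0.08 without those arrays, and stem cell regulators (-0.16; -0.43, -0.24 and 0.19 within the dates, 1 of 37 unadjusted, camera adjusted p = 0.0141) were at 0.11 without them (adjusted p = 0.829 for both with an estimated correlation). Glycolysis genes were higher by 0.18 (1 of 17 unadjusted, camera adjusted p = 0.000841, and adjusted p = 0.589 with an estimated correlation). With the replicate block the ATF4 targets passed too (-0.18, camera adjusted p = 0.069 without and 0.0224 with it). Without those arrays interferon-response genes passed upward (median 0.51, camera adjusted p = 0.000481, against 0.17 and 0.394 with them), and limma called 2 probe sets.

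The difference between the stimulation responses of KO and WT cells was tested as an interaction, and Ccn3 was the gene that passed. Its response was smaller in KO cells by -8.55 (SE 0.46, adjusted p = 0.000128; -9.72, -8.03 and -7.90 within the dates) and -6.86 (SE 0.42, adjusted p = 0.000268) on its 2 probe sets, the only ones called of 45037 (507 at an unadjusted p under 0.05, where 2252 are expected by chance). The model has no term for shared deviations of same-numbered arrays, so its p may be too high here too. Other genes are not shown to respond alike. Enah (-5.84, SE 0.69) and Stxbp6 (-3.04, SE 0.36), each with an adjusted p of 0.0728, did not pass, nor did Plxdc2 (-3.75, SE 0.61, adjusted p = 0.624) and Ccdc40 (-2.17, SE 0.32, adjusted p = 0.358). With the replicate block 4 probe sets passed, Enah among them (adjusted p = 0.000917). The call of Ccn3 was lost when all arrays of replicate 2 or all arrays of replicate 3 were left out (adjusted p up to 0.119). The interaction of Stat5b was 1.47 and that of Stat5a 1.06 (adjusted p = 1 for both), with KO values at background throughout. Over all probe sets, single genes called in WT but not in KO cells, such as Pim2 and Il2ra, are therefore not shown to respond differently. Adjusted over the list alone, the interaction was positive for 1 and negative for 3 of 19 STAT5 targets. Camera did not pass that list (adjusted p = 0.121), while fry taken over both directions gave an adjusted p of 0.000776. Some STAT5 targets besides Ccn3 may thus respond differently.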

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

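Of the tests below, those of a single date, of macrophages and of the ratio of response counts were chosen only after the result was seen.

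The response of Ccn3 to stimulation differed between genotypes by -8.55 and -6.86 (log2) on its 2 probe sets, which was picked out because the interaction of genotype and stimulation passed its test. With the replicate block both values stayed past the threshold (adjusted p = 0.000917 and 0.0023). Another 6 gene lists were picked out by the same test of the interaction, with camera and the preset correlation: the KO response was higher by a median of 0.665 for interferon response (adjusted p = 0.0248), 0.514 for immediate-early genes, 0.283 for ATF4 targets, 0.264 for mast cells and basophils and 0.332 for monocytes and macrophages, and it was lower by -0.167 for glycolysis (adjusted p = 0.0423 for each of these). None of these calls held with an estimated correlation, where the adjusted p was 0.825 for interferon response, 0.865 for immediate-early genes, 0.776 for monocytes and macrophages and 0.644 for the others. No member of these lists passed limma's test of the interaction (1 at an unadjusted p under 0.05, a monocyte and macrophage marker). Within the dates the medians were 0.96, 1.29 and -0.33 for interferon response, 0.60, 0.31 and 0.72 for immediate-early genes, 0.86, 0.07 and 0.10 for ATF4 targets, 0.39, 0.43 and 0.26 for mast cells, 0.21, 0.58 and 0.30 for monocytes, and 0.37, -0.35 and -0.53 for glycolysis. Glycolysis was lost with the replicate block (adjusted p = 0.0641). Immediate-early genes (0.433), ATF4 targets (0.333) and interferon response (0.202) were lost without WT stimulated 1 and KO unstimulated 1, where the medians were 0.31, 0.29 and 0.48. Mast cells (0.50, 0.00617), monocytes and macrophages (1.20, 0.00123) and glycolysis (-0.40, 8.23e-05) passed there with larger medians. Stem cell regulators (-0.35, 0.00123, against 0.05 with those arrays), erythroid genes (0.81, 0.00617, against 0.02) and endothelial and stromal genes (-0.33, 0.0115, against -0.09) passed only there.

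Interferon-response genes were higher in stimulated cells of both genotypes, with medians of 4.21 and 4.90 (log2). The samples of a single date are argued against as the source, since the second highest of the 3 date medians, averaged over the genotypes, was 5.55 (SD of the 6 medians 1.79). Whether the date is one of culture, sort or hybridization is not given. Macrophages among the stimulated cells cannot be told apart from a response of the KSL cells. KSL cells lack lineage markers by definition, which bears on macrophages present at the start and not on any arisen in culture. Of 15 macrophage transcripts 3 rose past the threshold in both genotypes (Cd14, Cd68 and Ctss). Mpeg1 (3.03 in WT and 4.45 in KO cells), Adgre1 (3.24 and 2.61) and Marco (1.07 and 2.11) went the same way, and camera passed the list upward in both (adjusted p = 0.00697 and 0.000656), though not with an estimated correlation (0.488 and 0.329), while Apoe fell (-4.54 and -3.81). C1qa stayed at background in all 4 groups, and 11 of the 15 transcripts lay above background in at least 1 group. Lyz2 and Csf1r, high before stimulation (11.4 to 11.9), decide nothing, and 14 of the 15 are also in the lists fixed earlier. Culture time or a component of the medium cannot be told apart from the cytokines, since 0 groups are described as cultured without them, so a direct response, one by way of secreted interferon and one to culture may each stand behind it.

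Genes lower in stimulated KO than in stimulated WT cells, Socs2, Enah, Plxdc2 and Cish besides Ccn3, were weighed against a variant carried along with the deleted locus and against the arrays of highest 3' to 5' difference. Of 18 called genes other than Stat5a and Stat5b, 0 are among the 100 nearest genes on either side of Stat5a, where 159 genes are measured (largest difference 2.37 in size, not past the threshold). This argues against carried variants that act on the genes beside them, and variants that act elsewhere stay open. Without WT stimulated 1 and KO unstimulated 1 the median ratio of the 25 lower probe sets' differences to those with them was 0.971. This ratio cannot decide on those arrays, since the probe sets were picked as called with them included. KO unstimulated 1 enters the spread but not the difference itself. Of the 29 called probe sets, 14 stayed called without both arrays. The loss of STAT5, which the design names, stays open and was not tested apart from a shift in the kinds of cells present. On such a shift the cell type lists bear without deciding. Between stimulated KO and WT cells monocyte and macrophage markers (median 0.61) and megakaryocyte genes (0.46) were higher and erythroid genes (-0.67, or -0.05 without both arrays) lower by camera. None of these calls held with an estimated correlation (adjusted p = 0.533).

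The KO response called 3374 probe sets and the WT response 2189, a ratio of 1.54. Without WT stimulated 1 and KO unstimulated 1 it was 1.32, and leaving out 1 array at a time moved it from 0.847 (without KO stimulated 1) to 3.48 (without WT stimulated 3; SD 0.803). The part of those arrays in it therefore cannot be told apart from the spread of the ratio. Of 100 splits of genotype within stimulation state, 47 gave a difference of counts at least as large as the real 1185 and the highest other was 3986, so chance assignment could account for it and the larger KO count is not shown to be a difference of genotype.

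Other splits of the arrays were counted for each comparison. The 6 arrays of a comparison of 3 against 3 give 10 splits, too few for a share under 0.05. In the WT response the real split called 2189 and the highest other 0, in the KO response 3374 and 0, and in unstimulated cells 4 and 0, so that 1 split, the real one, reached the real count in each. In stimulated cells 2 splits reached the real 29: the highest other called 63 and sets both arrays of the second date against both of the third, so it follows shared dates. The 3 other splits that part all dates called 0, and the replicate block called 44. For the interaction 18 of 100 splits reached the real count of 2. All 10 that keep the genotype groups of the stimulated arrays, the real one included, are among them. Ccn3 differs only there, so such splits carry its difference and the count cannot decide on chance. The other 8 part at most 4 of the 6 pairs of arrays of 1 date and stimulation state, and the 13 splits that break those groups and part all 6 called 0. The highest other, 196, sets the second date against the third in both stimulation states, which points to a structure of the samples by date. Among the 17 other splits that part as many dates the highest called 18, and this one exchanges the genotypes in stimulated cells only, so that it adds both genotype differences.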

How the results depend on the processing

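Chosen only after the result was seen were the background level as a lower limit and leaving out WT stimulated 1 and KO unstimulated 1. Every comparison kept some calls under each setting, except that the interaction had 0 calls without replicate 2 and without replicate 3. The counts moved, and unless the construction shows it the cause was not tested. The counts below are in the order WT response, KO response and stimulated genotype difference, against 2189, 3374 and 29. The replicate block gave 4633, 6368 and 44, and a random block 4065, 5714 and 56. Fewer were called with no moderation (1094, 1984, 14), with only the compared groups in the fit (1306, 2181, 9), with 1 probe set per gene, which tests fewer probe sets (1279, 1669, 17), and with values below background set to it (1028, 1712, 19). Without both arrays named above 15 were called in stimulated cells, 14 of them among the 29, and all 29 kept their sign; 2 against 4 were called in unstimulated cells, where the median of stem cell regulators turned from -0.16 to 0.11. The interaction, 2 calls, gave 4 with the replicate block, 5 with a random block, 4 without dim probe sets, 5 with trend and robust moderation and 1 with 1 probe set per gene. Leaving out 1 array or 1 replicate number gave 461 to 1720 in the WT response, 926 to 2969 in the KO response, 3 to 34 in stimulated and 1 to 5 in unstimulated cells, and 0 to 7 in the interaction. Single arrays that moved a count by more than 1.5 times were, in the WT response, WT stimulated 3 (955 without it) and WT unstimulated 1, 2 and 3 (1292, 1327 and 1315); in the KO response, KO stimulated 1 (1807) and KO unstimulated 2 and 3 (1995 and 1854); in stimulated cells, KO stimulated 1, 2 and 3 (15, 18 and 17) and WT stimulated 1 (18); and in the interaction, WT stimulated 2 and 3 (7 and 5). With values below background set to it the Ccn3 difference was 6.81 in the WT response and -6.81 in stimulated cells and in the interaction, past the threshold in each. Over the fits that left out arrays or replicates it ranged from 8.26 to 9.06 in the WT response, from -9.06 to -8.15 in stimulated cells and from -8.87 to -7.96 in the interaction, where its call was lost without replicate 2 and without replicate 3 (adjusted p up to 0.119). The correlation of the responses was 0.908 over all genes, and the slope 0.987 over all genes and 0.980 over genes called in WT cells. No named called gene changed direction: over its alternatives the call held in 521 of 566 cases in the WT response, 473 of 502 in the KO response, 239 of 328 in stimulated and 58 of 63 in unstimulated cells, and 47 of 51 in the interaction. The cases overlap, since all refit the same arrays. Under every alternative the call held for 9 of 27, 11 of 24, 3 of 16, 1 of 3 and 0 of 2 named probe sets, in the same order. The replicate block brought Stat5a in the WT response and Enah in the interaction past the threshold and ended the call of Ccr2. Signal over background limits folds: 52.0% of probe sets average below background, where Ccn3 lies in 3 of the 4 groups, so its fold is a bound.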

Other observations

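The tests of germ line genes and of NF-kappa-B targets were chosen only after the result was seen.

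Inflammatory genes such as Ptgs2 were among the largest rises, and a list of 25 NF-kappa-B targets without the genes already seen was tested, of which 24 are measured and none is in the other lists. In WT cells 9 rose, with a median of 1.89 (log2), and in KO cells 7 rose, with a median of 1.67. Relb, a subunit of NF-kappa-B, rose by 4.92 (SE 0.45, adjusted p = 0.000523) in WT and 5.04 (SE 0.45) in KO cells, Nfkb2 by 4.35 (SE 0.36) and 4.54 (SE 0.36), its regulator Bcl3 by 3.30 (SE 0.43) and 2.79 (SE 0.43), the chemokine Cxcl2 by 5.30 (SE 1.21) and 5.90 (SE 1.21) and the cytokine Tnf by 3.41 (SE 0.79) and 4.13 (SE 0.79). Camera passed the list upward in both genotypes (adjusted p = 1.88e-09 in WT and 4.81e-08 in KO cells), but the calls were lost with an estimated correlation (adjusted p = 0.139 and 0.171). A rise of NF-kappa-B targets may be part of the response of both genotypes. Not every member rose in both: Il1a (2.61, SE 0.61, and 0.17, SE 0.61) and Il1b (3.92, SE 0.93, and 2.16, SE 0.93) passed in WT cells only. Between stimulated KO and WT cells they differed by -2.46 (SE 0.61) and -2.32 (SE 0.93), and 0 members passed there.

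The germ line and pluripotency genes Ddx4 and Gdf3 were among the largest falls, and a list of 25 other such genes was tested. The test could not show a fall: 2 of the 25, Lin28a and Piwil2, lay above background in at least 1 group, and the others could not go lower. Camera gave an adjusted p of 0.285 in WT and 0.403 in KO cells. Piwil2 rose (2.48, SE 0.51, and 2.90, SE 0.51), and Lin28a did not pass (-0.68 and -0.99, SE 0.77 for both). Whether such genes fall as a group stays open.

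The 15 macrophage transcripts weighed above had a median of 1.07 in the WT and 1.24 in the KO response (camera adjusted p = 0.00697 and 0.000656; adjusted p = 0.488 and 0.329 with an estimated correlation).

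Transcripts of both sexes were measured on every array. Xist, which marks the inactive X chromosome of females, ranged from 11.4 to 14.1 over the 12 arrays, and the Y-linked genes Eif2s3y (9.93 to 11.6), Kdm5d (6.05 to 9.11) and Uty (5.27 to 8.11) were above background on 12 of 12 arrays. None of them passed in either response.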
